A study of Homo sapiens with 12 samples.

How the data were processed

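The series holds 12 Agilent 2-colour arrays of Ramos cells. On 6 arrays etoposide-treated RNA and on 6 anti-IgM-treated RNA was hybridised with untreated RNA, as 3 biological replicates per treatment, each with the dyes exchanged on a second array. Groups, replicate numbers and the dye of each channel were taken from the labels. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns, amplified and labelled with Agilent's low-input linear amplification kit. The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 9.5.1.1 per the submitters' processing notes. Per the file headers, these give mean and background signals as spot intensity on a linear scale and a log10 ratio of red (Cy5) to green (Cy3).

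The authors also deposited a table of averaged log10 ratios for both treatments. Its header describes treated over untreated, averaged over dye swaps and replicates. Over 40736 probes with 1 spot each, its values equalled minus the mean of the 4 dye-turned ratios of replicates 1 and 2, within 0.0001, for 100% of probes and both treatments, and with all 3 replicates for 0.34% (etoposide) and 0.36% (anti-IgM) of its non-zero values. Its values correlated with the log2 changes reported here at r = -0.96 for both treatments. The direction used here is that of the dyes in the labels, and no result was taken from that table.

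Mean signals were corrected with limma's normexp method (offset 50) against the background medians, and each array was normalised by loess, with control spots at weight 0. Outlier-flagged spots, 87 to 122 per array, and control spots were left out, spots of a probe were averaged, and ratios were turned to treated over untreated. The 2 arrays of a dye swap were averaged to 1 log2 ratio per replicate. Probes were kept if well above background in the treated channel of all arrays of either treatment or in the untreated channel of all 12 arrays, which left 24875 of 41000 probes. The kept probe with the highest mean signal stood for its gene. Probes were named through the RefSeq gene table of assembly GRCh38.p14, by the file's accession (23434 probes), another accession (411), symbol (2018) or synonym (966), and 14171 kept only the file's name. The build of the files' coordinates was not given in the sources used here, and no coordinates were used.

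One limma fit (lmFit and eBayes) of the 6 ratios, with 1 coefficient per treatment, tested each treatment against untreated cells and their difference, over 18282 genes with at least 2 ratios per treatment. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The treated and untreated RNA of a ratio share an array, so each ratio is paired by construction. Same-numbered ratios of the 2 treatments share their untreated extract per the labels, and their deviations from the treatment means correlated at 0.292, 0.505 and 0.365 across genes, so the numbers pair the samples. The main fit nevertheless took the 6 ratios as independent, and the replicate number as a block was an alternative for the difference. Where a probe was not well above background on any array of a group, the fold is a bound. The mean of the brighter group was set against the dimmer group's mean of, per array, the higher of its own value and the lowest signal among probes well above background, per channel after loess and Aquantile normalisation. Probes of 1 gene can disagree, and their range is given where it matters.

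The 24 gene lists were fixed before the data were examined. They cover p53 targets, NF-kB targets, immediate-early genes, CREB and CRTC targets, B-cell receptor signalling components, germinal centre B-cell genes, plasma cell genes, B-cell activation markers, chemokines with cytokines and trafficking receptors, G1/S and DNA replication genes, G2/M and mitosis genes, histone genes, the BCL2 family, DNA damage response and repair genes, ribosome biogenesis genes, interferon-stimulated genes, cholesterol synthesis genes, unfolded protein and integrated stress response genes, heat-shock genes, glycolysis and hypoxia genes, antigen presentation genes, and markers of T and NK, myeloid, and epithelial and fibroblast cells. Lists share members. The 22 lists with at least 3 tested genes were tested with limma's camera (preset correlation 0.01), adjusted over the lists of a comparison. None of these calls held with an estimated correlation, which rests on few residual degrees of freedom, and its adjusted p is printed beside each. The estimates ran from -0.05 for plasma cell genes to 0.51 for unfolded protein and integrated stress response genes. They were 0.42 for mitosis genes, 0.33 for NF-kB targets and 0.08 for immediate-early genes. Where an estimate lies above the preset 0.01, the p-values of the preset test may be too small. Counts of list members are adjusted over all genes unless said otherwise.

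Named genes follow a rule fixed at the same time. It takes the 12 largest increases and the 12 largest decreases per treatment among genes past the threshold with a symbol and the same sign in all 3 replicates, 6 each way for the difference, up to 4 members per list and comparison past the threshold with the largest change (up to 2 if none passed), and, where measured, BCL6, PRDM1, TCL1A, MYC, CRTC2, CDKN1A, EGR1 and IRF4. The text may name fewer, in order of size, and some genes that the rule takes are not reported here. The values of a gene named for one comparison may be given for the others.

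The fit was tested on simulated ratios with the spread of the real genes and a shared untreated part. Among 18282 genes, 67 were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. The etoposide test recovered 68.7%, 100% and 100% of them. The anti-IgM test recovered 73.1%, 98.5% and 100%, and the test of the difference 11.9%, 100% and 100%. Of the unchanged genes the 3 tests called 17, 13 and 2, among 196, 194 and 143 genes called. Far fewer genes were changed there than were called in the real data, and loess was not simulated. Recovery in the real data may therefore differ. Camera called 6 of 6 lists shifted by 0.5 and 0 of the others in each comparison. The simulated genes varied independently of each other. This result therefore does not test camera on lists whose genes vary together.

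Scans (2 batches, the second with replicate 3 of both treatments) were tested as a block. Slides (3) entered as a random block, in a fit that does not test a slide effect. Slide 1 held replicates 1 and 2 of etoposide, slide 2 those of anti-IgM, and slide 3 replicate 3 of both. For the difference, slide and treatment therefore cannot be told apart in replicates 1 and 2. Alternatives changed the background correction, the normalisation within and between arrays, the filter on dim probes, the choice of probe, the averaging of dye swaps, the blocks, the samples in the fit and the kind of set test, and left out each replicate in turn. Scan batch as a block in the list tests was added after the data were seen. A separate-channel fit of the 9 extracts, with and without the replicate number as a block, was the paired and unpaired alternative. Analyses used R 4.3.3 and limma 3.58.1, and figures were drawn with matplotlib.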

Results

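Gene expression was measured in Ramos cells, a human Burkitt's lymphoma line with features of germinal centre B cells, the antibody-diversifying B cells of the lymph node. Cultures received 20 µM etoposide, a poison that traps topoisomerase II on cut DNA, or 10 µg/ml anti-IgM, an antibody that crosslinks the B-cell receptor, for 6 h, or were left untreated. Each treatment had 3 biological replicates, and each replicate was hybridised against untreated RNA on 2 arrays with the dyes exchanged, which made 12 arrays from 9 RNA extracts. Replicates of the same number shared their untreated extract between the treatments. Between 59.2% and 69.7% of gene spots per channel were well above background, no spot was saturated, and the number of arrays limits the precision. After filtering, 18282 genes or unnamed transcripts were tested, 11892 of them with a gene symbol. All changes are log2 ratios of treated to untreated cells with the standard error of the limma fit (n = 3). That error rests on 1 moderated spread per gene, shared by both treatments, and not on the 3 replicates of a treatment alone. For TNFAIP2 with etoposide it was 0.31, while those replicates had an SD of 0.96. The direction of the changes follows the dyes in the labels. It opposes the direction of the authors' deposited table, where EGR1 has a log10 value of -1.89 with anti-IgM, whereas the arrays under the labels' dyes gave EGR1 a log2 change of 5.42 ± 0.41.

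The first comparison asked which transcripts change when topoisomerase II is poisoned. After etoposide, 20 of 26 germinal centre genes, 20 of 22 B-cell receptor signalling components and 20 of 26 mitosis genes fell, while 13 of 22 NF-kB targets, 14 of 23 immediate-early genes and 13 of 22 G1/S genes rose. These 6 lists passed camera with its preset correlation, and with an estimated correlation none did (adjusted p = 0.298 to 0.464). The 5060 genes that rose and the 5697 that fell made up 58.8% of those tested, and 637 rose and 1585 fell by at least 2-fold. With Agilent's own ratios the balance turned, and 6383 rose and 5022 fell. Loess centres the ratios of each array, and the median change over all tested genes was 0.008. Rises and falls in all comparisons are thus relative to that centre. Such centring assumes that most genes do not change, which the share called here puts in question. The largest increase was that of TNFAIP2, a TNF-inducible gene, at 3.71 ± 0.31. GPR183, a receptor that guides B-cell migration, rose by 3.23 ± 0.20, and EBI3, a cytokine subunit, by 3.03 ± 0.25. CSRP2 followed at 2.86 ± 0.12, ZNF425 at 2.84 ± 0.06, the stress-inducible IER3 at 2.67 ± 0.11 and HEXIM1, an inhibitor of transcription elongation, at 2.64 ± 0.09. The largest decrease was that of the zinc-finger gene ZNF385B at -4.49 ± 0.27, followed by the B-cell transcription repressor BACH2 at -3.73 ± 0.12, SIPA1L3 at -3.59 ± 0.15, the splicing regulator MBNL1 at -3.37 ± 0.11 and SSBP2 at -3.32 ± 0.11. OSBPL10, PLCG2, DEPTOR, TMEM131L, ABR and EHMT1 followed, between -3.30 and -3.19. Adjusted p was at most 4.46e-05 for these genes. Different probes of a gene did not always move equally. Those of ZNF385B spanned -4.49 to -1.92, those of MBNL1 -3.37 to -0.33 and those of EBI3 1.30 to 3.03.

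Of 26 measured germinal centre B-cell genes, 20 fell and 0 rose, with a median change of -1.26 (camera, adjusted p = 5.86e-06). With an estimated correlation this list had an adjusted p = 0.328. Members included KLHL6 at -2.93 ± 0.10, POU2AF1, a B-cell transcription coactivator, at -2.85 ± 0.08, and MYBL1 at -2.56 ± 0.27. BCL6, the master repressor of the germinal centre state, was at -2.19 ± 0.10 and TCL1A, a coactivator of AKT, at -1.58 ± 0.14. Of 22 B-cell receptor signalling components, 20 fell and 0 rose (median -1.26, adjusted p = 7.83e-07, and adjusted p = 0.298 with an estimated correlation). Among these were PLCG2, the phospholipase downstream of the receptor, at -3.29 ± 0.13, the kinase LYN at -2.42 ± 0.15 and the inhibitory coreceptor CD72 at -2.19 ± 0.12. MYC, the oncogene placed under immunoglobulin control in Burkitt's lymphoma, was at -1.99 ± 0.21, although its 3 probes spanned -1.99 to -0.01.

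The cell-cycle lists moved apart. Of 26 G2/M and mitosis genes, 20 fell and 0 rose (median -1.02, adjusted p = 5.86e-06, and adjusted p = 0.412 with an estimated correlation), with the mitotic kinase PLK1 at -2.47 ± 0.10, CDC20, an activator of the anaphase-promoting complex, at -2.25 ± 0.09 and HMMR at -2.06 ± 0.12. Of 22 G1/S and DNA replication genes, 13 rose and 1 fell (median 0.28, adjusted p = 0.00459, and adjusted p = 0.401 with an estimated correlation), led by the cyclins CCNE2 at 1.57 ± 0.10 and CCNE1 at 1.41 ± 0.08. Of 28 DNA damage response and repair genes, 19 fell and 3 rose (median -0.50, adjusted p = 0.00111, and adjusted p = 0.412 with an estimated correlation). The damage-sensing kinase ATM was at -1.58 ± 0.10, with probes from -1.58 to -0.55, and TOP2B, 1 of the etoposide targets, at -1.51 ± 0.10. Among 24 targets of p53, 10 rose and 6 fell, and the list did not shift past the threshold (median 0.17, adjusted p = 0.147). It passed upwards with fry, limma's rotation test of a list on its own (adjusted p = 0.00256). FAS, a death receptor, rose by 1.89 ± 0.24 and the cyclin-dependent kinase inhibitor CDKN1A by 1.15 ± 0.10, while RRM2B was at -1.34 ± 0.10. In the separate-channel fit CDKN1A was at 0.56, and its call held with the replicate number as a block (adjusted p = 0.0265) and was lost without it (adjusted p = 0.581).

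Of 22 NF-kB targets, 13 rose and 2 fell (median 0.94, adjusted p = 0.00111, and adjusted p = 0.464 with an estimated correlation), among them CD83 at 2.06 ± 0.13 and CD40 at 2.03 ± 0.15. Of 23 immediate-early genes, 14 rose and 2 fell (median 0.67, adjusted p = 0.000584, and adjusted p = 0.350 with an estimated correlation), with the AP-1 subunit JUNB at 2.23 ± 0.09 and IER5 at 2.22 ± 0.17, with its other probe at 0.85. EGR1 was at 0.81 ± 0.41 and did not pass (adjusted p = 0.128), but was at 1.45 and passed without replicate 2 (adjusted p = 0.0108). Replicate 2 was at -0.48 and the others at 1.29 and 1.62. Of 14 B-cell activation markers, 8 rose and 2 fell (median 0.80, adjusted p = 0.0120, and adjusted p = 0.412 with an estimated correlation), with ICAM1 at 1.42 ± 0.12. Of 12 chemokines, cytokines and trafficking receptors, 7 rose and 0 fell (median 0.59, adjusted p = 0.00529, and adjusted p = 0.350 with an estimated correlation). The 18 CREB and CRTC targets, of which 8 rose and 4 fell, had a median of 0.51 and missed the threshold (adjusted p = 0.0546), which they passed without replicate 1 (adjusted p = 0.0498) and without replicate 3 (adjusted p = 0.0410). CRTC2, which encodes a coactivator of CREB, was at 0.20 ± 0.09 (adjusted p = 0.0861). It passed in the separate-channel fit with the replicate number as a block (adjusted p = 0.0447) and without replicate 1 (adjusted p = 0.0419). IRF4, a regulator of plasma cell differentiation, was at 0.19 ± 0.36 (adjusted p = 0.686), and no probe of PRDM1, another such regulator, passed the filter.

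Of 21 cholesterol synthesis genes, 10 fell and 3 rose (median -0.25, adjusted p = 0.0450, and adjusted p = 0.665 with an estimated correlation). This call was lost without replicate 1 (median -0.27, adjusted p = 0.130), without replicate 2 (median -0.24, adjusted p = 0.0637), with scan batch as a block (median -0.25, adjusted p = 0.0504) and with median centring in place of loess (median -0.28, adjusted p = 0.0848). Without replicate 3 the median was -0.40 and the call was kept. The other tested lists did not shift past the threshold. They were plasma cell genes (5 of 17 rose and 5 fell), histone genes (9 of 15 rose and 5 fell), the BCL2 family (7 of 17 rose and 4 fell), ribosome biogenesis genes (2 of 20 rose and 9 fell) and interferon-stimulated genes (7 of 16 rose and 5 fell). In the remaining lists, 3 of 15 unfolded protein and integrated stress response genes rose and 3 fell, 2 of 9 heat-shock genes rose and 4 fell, 0 of 20 glycolysis and hypoxia genes rose and 8 fell, and 5 of 13 antigen presentation genes rose and 2 fell. Adjusted p for these ranged from 0.0980 to 0.994, and the lowest, that of glycolysis and hypoxia genes, passed without replicate 1 (adjusted p = 0.0442) and without replicate 2 (adjusted p = 0.0422). The median and the mean of plasma cell genes (-0.06 and 0.02) and of interferon-stimulated genes (-0.13 and 0.09) differed in sign. The linker histone gene H1-5 was not well above background in etoposide-treated cells on any of 6 arrays and was at least 1.93-fold lower there. Few markers of other cells were left for testing after the filter on dim probes. These were 7 of the 15 T and NK cell, 1 of the 9 myeloid and 2 of the 10 epithelial and fibroblast markers on the array. Of the 7 T and NK cell markers 1 fell (list adjusted p = 0.595). The 1 tested myeloid marker, CD14, was at 0.10 ± 0.06 (adjusted p = 0.215). Of 2 epithelial and fibroblast markers KRT18 was at 0.51 ± 0.11, with probes from 0.25 to 0.51, a call lost without replicate 3 (adjusted p = 0.0547). The separate-channel fit with the replicate number as a block put CD14 at 0.32 (adjusted p = 0.0396). Adjusted over the list alone, 3 NF-kB targets and 3 activation markers fell, 1 germinal centre gene rose and 21 fell, 14 G1/S genes rose, 4 repair genes rose and 6 antigen presentation genes rose, and the other counts were as given.

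With scan batch as a block 10962 genes passed for etoposide, and within the first batch, which held replicates 1 and 2, 8496 passed. The second batch held 1 ratio per treatment and allowed no test. Both batches entered the calls, so agreement in sign between them is no independent test. The medians in the 2 batches were -1.25 and -1.14 for germinal centre genes, -1.17 and -1.47 for receptor signalling components and 0.29 and 0.26 for G1/S genes. A fit that ignored the pairing of treated and untreated extracts called 4904 genes. The medians of some lists depended on the processing although the call was kept. With Agilent's ratios immediate-early genes were at 1.02 and chemokines, cytokines and trafficking receptors at 1.16, the latter were at 0.27 with no filter on dim probes, and G1/S genes were at 0.43 with median centring.

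The second comparison asked which transcripts respond to B-cell receptor crosslinking. With anti-IgM, 18 of 23 immediate-early genes, 10 of 14 activation markers, 9 of 12 chemokines, cytokines and trafficking receptors and 11 of 13 antigen presentation genes rose, and 15 of 22 G1/S genes and 13 of 26 germinal centre genes fell. These 6 lists passed camera with its preset correlation, and with an estimated correlation none did (adjusted p = 0.0826 to 0.317). In all 2986 genes rose and 3705 fell, 36.6% of those tested, of which 467 rose and 351 fell by at least 2-fold. The zinc-finger transcription factors EGR2 and EGR1 rose by 6.94 ± 0.32 and 5.42 ± 0.41, and both were well above background in untreated cells on 5 of 6 arrays. The nuclear receptor NR4A3 rose by 5.20 ± 0.15, with its other probe at 1.41. GPR183 rose by 5.03 ± 0.20, CCR7, the receptor that draws lymphocytes to T-cell zones, by 4.77 ± 0.07 and the chemokine CCL4 by 4.51 ± 0.20. GEM, a small GTP-binding protein, was not well above background in untreated cells on any of 6 arrays and rose at least 17.6-fold (adjusted p = 1.40e-05). RGS1, CORO6, the inhibitory receptor PDCD1, the phosphatase DUSP5 and EGR4 rose by 3.87 to 4.27. The largest decrease was that of DEPTOR, an inhibitor of mTOR, at -3.01 ± 0.12, followed by ZNF385B at -2.43 ± 0.27 (other probe -1.53), RNF144B at -2.28 ± 0.11, GSDME at -2.25 ± 0.12 and LZTS1 at -2.16 ± 0.20. PRKAR2B, SORBS2, STOX2, CDHR3, PALLD, BEST3 and GPR146 fell by between -2.14 and -1.89. Adjusted p was at most 0.00098 for these genes.

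Of 23 immediate-early genes 18 rose and 1 fell (median 1.46, adjusted p = 3.20e-12, and adjusted p = 0.0826 with an estimated correlation), and of 18 CREB and CRTC targets 15 rose and 1 fell (median 1.45, adjusted p = 7.26e-09, and adjusted p = 0.0826 with an estimated correlation). FOS was at 3.32 ± 0.10 and SGK1 at 3.38 ± 0.37. CRTC2 itself was at 0.27 ± 0.09 and missed the threshold (adjusted p = 0.0503), which it passed with scan batch as a block (adjusted p = 0.0409) and without replicate 1 (adjusted p = 0.0358). Of 22 NF-kB targets 16 rose and 1 fell (median 1.04, adjusted p = 1.28e-07, and adjusted p = 0.256 with an estimated correlation), with CCL3 at 3.40 ± 0.14 and TNF at 3.31 ± 0.27, whose other probe gave 2.02. Of 14 activation markers 10 rose and 1 fell (median 1.88, adjusted p = 1.53e-07, and adjusted p = 0.113 with an estimated correlation), with the adhesion receptor CD44 at 3.35 ± 0.17 and SLAMF1 at 2.68 ± 0.17. Of 12 chemokines, cytokines and trafficking receptors 9 rose and 0 fell (median 1.91, adjusted p = 4.05e-07, and adjusted p = 0.0826 with an estimated correlation). Of 13 antigen presentation genes 11 rose and 0 fell (median 0.84, adjusted p = 1.53e-07, and adjusted p = 0.175 with an estimated correlation), with HLA-DQB1 at 1.41 ± 0.09 (probes from 0.75 to 1.59) and CIITA, the transactivator of MHC class II genes, at 1.11 ± 0.11 (probes from 0.35 to 1.15).

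Of 21 cholesterol synthesis genes 14 rose and 0 fell (median 0.45, adjusted p = 4.43e-06, and adjusted p = 0.317 with an estimated correlation), with INSIG1 at 1.41 ± 0.15 and SC5D at 1.38 ± 0.10. Of 15 unfolded protein and integrated stress response genes 8 rose and 0 fell (median 0.85, adjusted p = 0.00306, and adjusted p = 0.417 with an estimated correlation), with the transcription factor DDIT3 at 1.75 ± 0.32. This call was lost with fry (adjusted p = 0.0706). Of 17 plasma cell genes 10 rose and 3 fell (median 0.28, adjusted p = 0.00306, and adjusted p = 0.113 with an estimated correlation). SLAMF7 was at 3.79 ± 0.08 and the chaperone HSP90B1 at 1.71 ± 0.10, whereas TNFRSF17, the receptor BCMA, was at -1.18 ± 0.17.

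Of 26 germinal centre B-cell genes 13 fell and 4 rose (median -0.44, adjusted p = 0.0182, and adjusted p = 0.317 with an estimated correlation), a call lost with median centring in place of loess (adjusted p = 0.0563). TCL1A was at -1.81 ± 0.14, MYBL1 at -1.72 ± 0.27 and ELL3 at -1.61 ± 0.13. BCL6 was at -0.51 ± 0.10 (adjusted p = 0.0057), a call lost without replicate 1 (adjusted p = 0.0660). MYC was at -0.84 ± 0.21, with probes from -0.84 to 0.05, and its call was lost without replicate 2, at -0.51 (adjusted p = 0.0538). IRF4 was at -0.35 ± 0.36 (adjusted p = 0.492), and at -0.91 without replicate 1, where it passed (adjusted p = 0.0294). Replicate 1 was at 0.78 and the others at -0.75 and -1.07. Of 22 G1/S and DNA replication genes 15 fell and 0 rose (median -0.35, adjusted p = 7.32e-06, and adjusted p = 0.113 with an estimated correlation), with E2F2 at -1.17 ± 0.13, whose probes spanned -1.17 to -0.23, and the uracil-DNA glycosylase UNG at -0.79 ± 0.08. Of 26 G2/M and mitosis genes 8 fell and 1 rose (median -0.18, adjusted p = 0.0259, and adjusted p = 0.605 with an estimated correlation), with HMMR at -0.91 ± 0.12. Of 28 repair genes 10 fell and 2 rose (median -0.18, adjusted p = 0.0193, and adjusted p = 0.417 with an estimated correlation), with the checkpoint kinase CHEK2 at -1.52 ± 0.07. Both the mitosis and the repair call were lost without replicate 2 (adjusted p = 0.0657 and 0.0795) and with median centring (adjusted p = 0.0725 and 0.0683), and the mitosis call also with fry (adjusted p = 0.125).

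Receptor signalling components went both ways, and 8 of 22 rose and 6 fell (adjusted p = 0.464). The phosphatase PTPN6 was at 1.82 ± 0.10 and CD72 at 1.71 ± 0.12, and the kinase BLK at -1.46 ± 0.15. Of 24 targets of p53, 5 rose and 10 fell (adjusted p = 0.322), with CDKN1A at 2.61 ± 0.10 and DDB2 at -1.33 ± 0.07. In the BCL2 family 6 of 17 rose and 2 fell (adjusted p = 0.0715, and adjusted p = 0.0150 without replicate 3), with HRK at 1.60 ± 0.14 (1.07 in the mean of its probes), BIK at 1.40 ± 0.08 and BCL2A1, whose probes spanned 1.24 to 3.57. Histone genes (2 of 15 rose and 3 fell), ribosome biogenesis genes (2 of 20 rose and 1 fell), interferon-stimulated genes (1 of 16 rose and 6 fell), heat-shock genes (1 of 9 rose and 2 fell) and glycolysis and hypoxia genes (3 of 20 rose and 2 fell) did not shift past the threshold, with adjusted p from 0.171 to 0.708. The median and the mean of heat-shock genes (-0.02 and 0.01) differed in sign. Of 7 T and NK cell markers 4 rose and 1 fell (list median 0.62, adjusted p = 0.0925). The list passed without replicate 3 (median 0.52, adjusted p = 0.04215) and with Agilent's ratios (median 1.33, adjusted p = 0.0428). They included the costimulatory receptor CD28 at 1.60 ± 0.29 and IL7R at 1.38 ± 0.28 (2.48 and 2.16 with Agilent's ratios), which were well above background in untreated cells on 5 and 4 of 6 arrays. CD14 was at -0.00 ± 0.06 and KRT18 at -0.07 ± 0.11, and neither passed. Adjusted over the list alone, 19 immediate-early genes, 12 plasma cell genes, 15 cholesterol synthesis genes and 12 antigen presentation genes rose, 6 germinal centre genes rose and 14 fell, 18 G1/S genes fell, 11 repair genes fell, 6 targets of p53 rose, 6 histone genes fell, 3 heat-shock genes fell, and 0 mitosis genes rose. No glycolysis gene and no ribosome biogenesis gene fell on that scale, and the other counts were as given.

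With no filter on dim probes the medians of activation markers and of chemokines, cytokines and trafficking receptors were 1.24 and 0.85, with Agilent's ratios that of plasma cell genes was 0.50, and without replicate 1 that of unfolded protein genes was 0.55, all with the call kept. Without replicate 1, 3956 genes passed for anti-IgM, and without the pairing of treated and untreated extracts 1222 did. With scan batch as a block 6972 passed, and within the first batch 4839 did. The medians in the 2 batches were 1.56 and 1.31 for immediate-early genes and -0.52 and -0.30 for germinal centre genes.

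**Figure D1:**
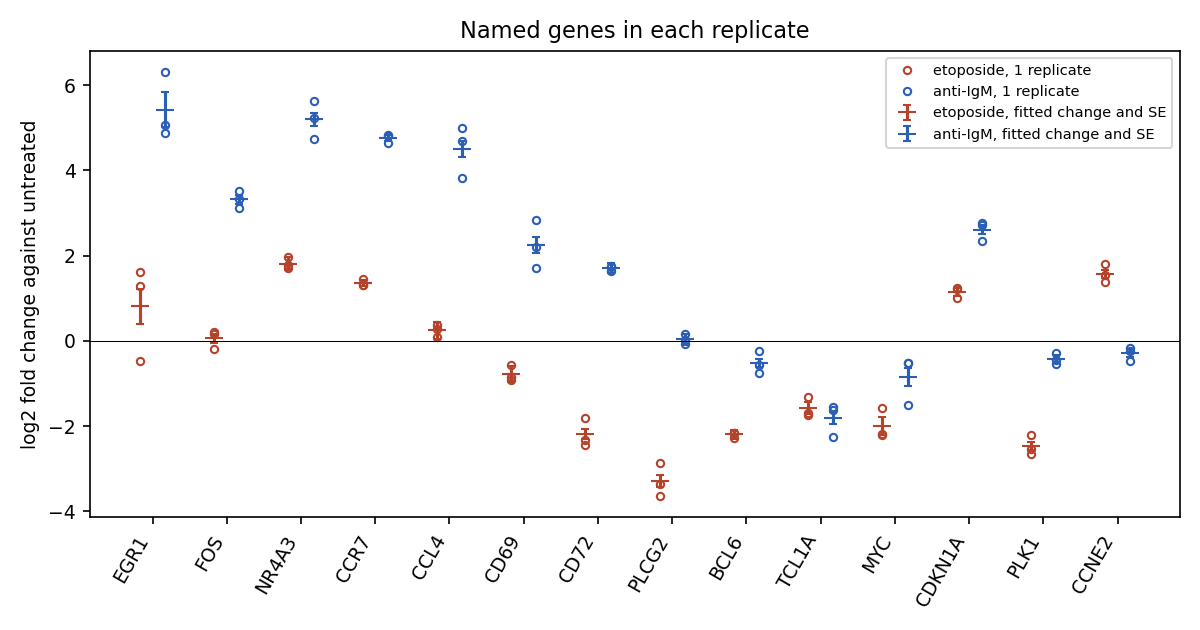
Log2 fold change against untreated cells (vertical axis) of 14 genes named in the text. Open circles are the 3 replicates of each treatment, and bars give the fitted change with its standard error. FOS stood at 3.32 with anti-IgM and 0.07 with etoposide, and PLCG2 at -3.29 with etoposide and 0.04 with anti-IgM.

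Etoposide and anti-IgM were compared directly through the difference of their log2 ratios. In replicates 1 and 2 the 2 treatments lay on different slides, so slide cannot be told apart from treatment there. After etoposide, 16 of 22 receptor signalling components, 16 of 21 cholesterol synthesis genes, 14 of 23 immediate-early genes and 10 of 26 germinal centre genes were lower than after anti-IgM, and 19 of 22 G1/S genes were higher. These 5 lists passed camera with its preset correlation, and with an estimated correlation none did (adjusted p = 0.225 to 0.347). In all, 3727 genes were higher and 4333 lower after etoposide than after anti-IgM, and 2324 of them differed by at least 2-fold. With Agilent's own ratios 4866 were higher and 3734 lower. TNFAIP2 differed most on the higher side, by 5.16 ± 0.44, followed by APOLD1 at 3.24 ± 0.24, ZNF425 at 3.15 ± 0.09, the interleukin receptor IL11RA at 2.90 ± 0.24 (other probe 1.56), ATP6V1G3 at 2.63 ± 0.20 (5.13 with Agilent's ratios) and N4BP2L1 at 2.52 ± 0.24. On the lower side stood EGR2 at -6.63 ± 0.45, RGS1 at -4.97 ± 0.20, EGR1 at -4.61 ± 0.58, the acid phosphatase ACP5 at -4.33 ± 0.22 and CCL4 at -4.26 ± 0.28. GEM was also lower, but its ratios are set against untreated cells in which it was not well above background, so the size of its difference is uncertain (-4.35 in the fit and -7.57 with Agilent's ratios).

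Of 22 receptor signalling components 16 were lower and 0 higher after etoposide than after anti-IgM (median -1.08, adjusted p = 4.03e-06, and adjusted p = 0.225 with an estimated correlation), with CD72 at -3.91 ± 0.17, PLCG2 at -3.33 ± 0.19 and PTPN6 at -3.14 ± 0.14. Of 26 germinal centre genes 10 were lower and 1 higher (median -0.64, adjusted p = 0.00216, and adjusted p = 0.347 with an estimated correlation), with KLHL6 at -3.43 ± 0.15 and the transcription factor MEF2C at -3.16 ± 0.18. The difference was -1.68 ± 0.14 for BCL6 and for MYC -1.15 ± 0.29, with probes from -1.15 to -0.06. The MYC call was lost without replicate 3 (adjusted p = 0.127) and with scale normalisation between arrays (adjusted p = 0.100). TCL1A (0.23 ± 0.20), CRTC2 (-0.07 ± 0.13) and IRF4 (0.53 ± 0.51) had differences that did not pass. Of 22 G1/S genes 19 were higher and 0 lower (median 0.75, adjusted p = 2.05e-06, and adjusted p = 0.225 with an estimated correlation), with CCNE2 at 1.86 ± 0.14, and of 26 mitosis genes 17 were lower and 0 higher (median -0.83, adjusted p = 6.36e-05, and adjusted p = 0.355 with an estimated correlation), with PLK1 at -2.05 ± 0.14. Of 21 cholesterol synthesis genes 16 were lower and 1 higher (median -0.93, adjusted p = 1.69e-05, and adjusted p = 0.347 with an estimated correlation).

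Immediate-early genes (14 of 23 lower and 5 higher, adjusted p = 0.00575), CREB and CRTC targets (10 of 18 lower and 2 higher, adjusted p = 0.00270), antigen presentation genes (10 of 13 lower and 0 higher, adjusted p = 0.00149) and glycolysis and hypoxia genes (7 of 20 lower and 1 higher, adjusted p = 0.0266) were also lower after etoposide. With an estimated correlation these had adjusted p = 0.347, except glycolysis and hypoxia genes, with adjusted p = 0.542. Median centring ended the call of glycolysis and hypoxia genes and took their median from -0.32 to -0.18 (adjusted p = 0.0562). The difference also passed for activation markers (8 of 14 lower and 4 higher, adjusted p = 0.0427, with CD69 at -3.02 ± 0.26), chemokines, cytokines and trafficking receptors (7 of 12 lower and 2 higher, adjusted p = 0.0377), plasma cell genes (9 of 17 lower and 2 higher, adjusted p = 0.0427) and repair genes (16 of 28 lower and 5 higher, adjusted p = 0.0427). With an estimated correlation their adjusted p was 0.347 to 0.492. Without replicate 2 these 4 calls were lost, with adjusted p from 0.0512 to 0.0791, that of activation markers was also lost without replicate 1 (adjusted p = 0.0538), and that of repair genes without replicate 3 (adjusted p = 0.0862). The calls of plasma cell genes and of repair genes were also lost with median centring (adjusted p = 0.0562 for both).

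Unfolded protein and integrated stress response genes (5 of 15 lower and 1 higher, adjusted p = 0.0627) and interferon-stimulated genes (6 of 16 higher and 2 lower, adjusted p = 0.0578) missed the threshold. With the replicate number as a block on the 6 ratios both passed, with adjusted p = 0.0169 and 0.0451, as they did with scan batch as a block (adjusted p = 0.0426 and 0.0408), without replicate 1 (adjusted p = 0.0148 and 0.0370) and without replicate 3 (adjusted p = 0.0280 and 0.0384). Targets of p53 (9 of 24 higher and 4 lower), NF-kB targets (7 of 22 higher and 8 lower), histone genes (8 of 15 higher and 3 lower), the BCL2 family (4 of 17 higher and 4 lower), ribosome biogenesis genes (2 of 20 higher and 8 lower), heat-shock genes (1 of 9 higher and 2 lower) and T and NK cell markers (4 of 7 lower and 0 higher) did not differ past the threshold as lists, with adjusted p from 0.108 to 0.659. T and NK cell markers passed with Agilent's ratios, where their median went from -0.71 to -1.51 (adjusted p = 0.0432), and ribosome biogenesis genes with no filter on dim probes (adjusted p = 0.0367). The median and the mean of the BCL2 family (0.01 and -0.29) differed in sign. Within it BIK differed by -3.33 ± 0.11. CD14 differed by 0.10 ± 0.09 (adjusted p = 0.392). In the separate-channel fit it differed by 0.55, and passed with the replicate number as a block (adjusted p = 0.0029) and without it (adjusted p = 0.0418). KRT18 differed by 0.58 ± 0.16, with probes from 0.18 to 0.58, a call lost with the mean of its probes (adjusted p = 0.0538), without replicate 2 (adjusted p = 0.0706) and without replicate 3 (adjusted p = 0.0890). Adjusted over the list alone, 9 activation markers, 11 antigen presentation genes, 6 unfolded protein genes, 3 interferon-stimulated genes and 4 histone genes were lower, 20 G1/S genes and 6 repair genes were higher, both epithelial markers were higher, and the other counts were as given.

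With no filter on dim probes the medians of immediate-early genes, CREB and CRTC targets and chemokines, cytokines and trafficking receptors were -0.59, -0.46 and -0.30, with the calls kept. Without replicate 1, 5370 genes differed. With scan batch as a block 8327 did, and within the first batch 5541 did. The medians in the 2 batches were -1.08 and -1.28 for receptor signalling components and 0.77 and 0.63 for G1/S genes.

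**Figure D2:**
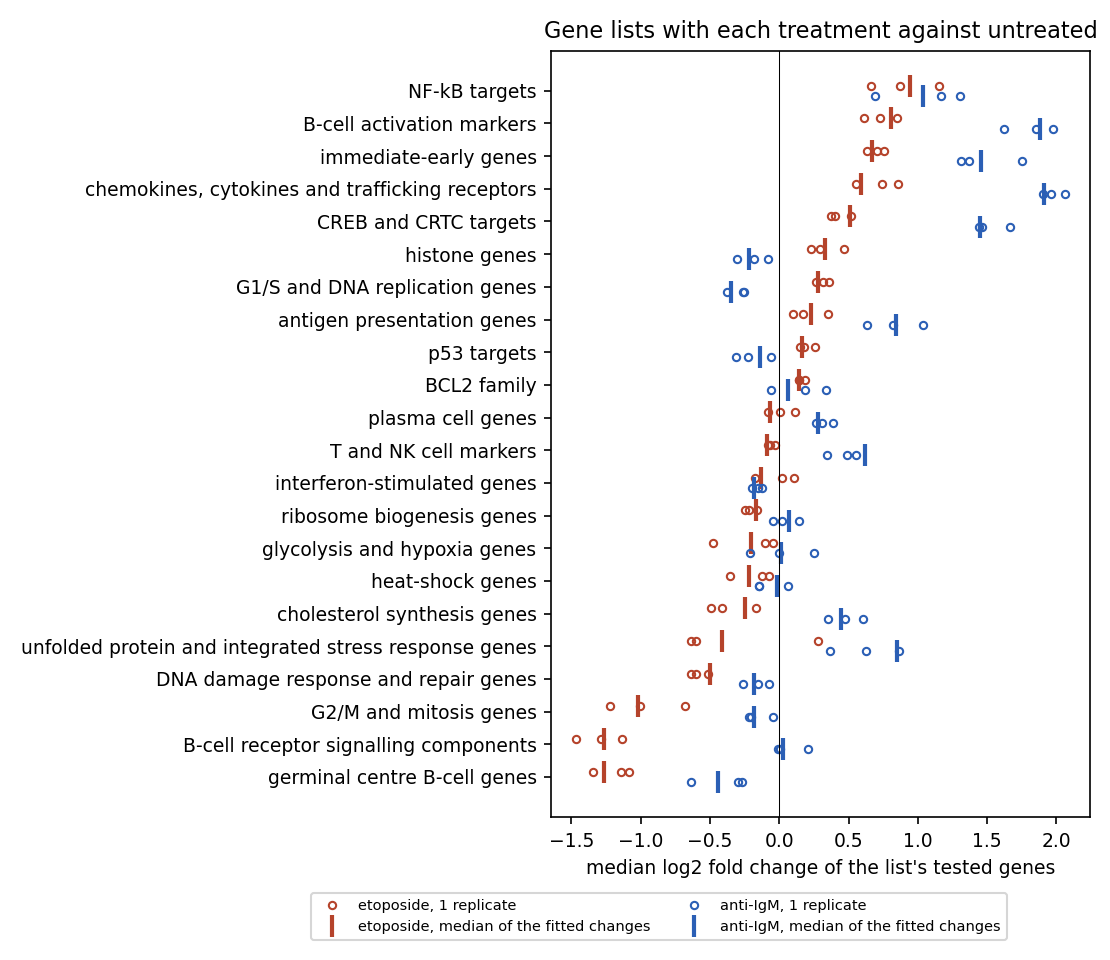
Median log2 fold change against untreated cells (horizontal axis) of the tested genes in each of 22 gene lists. Circles are single replicates (n = 3 per treatment), and vertical bars are the median of the fitted changes. Receptor signalling components lay at -1.26 with etoposide and 0.03 with anti-IgM, and activation markers at 0.80 and 1.88.

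Across genes, which are not independent replicates, the 2 responses correlated with a Pearson r of 0.271 and a Spearman rho of 0.277. The r was 0.286 within the first scan batch and 0.254 in the second, which held 1 ratio of each treatment. Because both treatments were set against the same untreated RNA, unchanged groups would correlate too, with a mean r of 0.399 in 20 simulations. The observed covariance was 0.0856 and that of the simulated unchanged groups 0.0042. Ratios of different replicate numbers, which share no untreated RNA, had a mean covariance of 0.0803 and r between 0.211 and 0.245. Of the genes called for both treatments, 3333 had the same direction, and independent lists of those sizes would share 1981. Of these, 1229 rose in both, where independent lists would share 826, and 2104 fell in both, against 1155. In the simulations of unchanged groups at most 1 gene was called the same way in both. No gene was changed there, so hardly any call could arise by design. That count does not show how far shared untreated RNA raises the overlap among called genes. Without replicate 1 the shared calls numbered 1884. With 3 untreated extracts the controls could not be split into groups of 2, and part of the excess may come from the shared untreated RNA. GPR183 and CD83 were among the genes that rose with both treatments, and ZNF385B, DEPTOR, BCL6 and TCL1A among those that fell with both. Opposite directions were called for 1312 genes, where independent lists would give 1956.

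**Figure D3:**
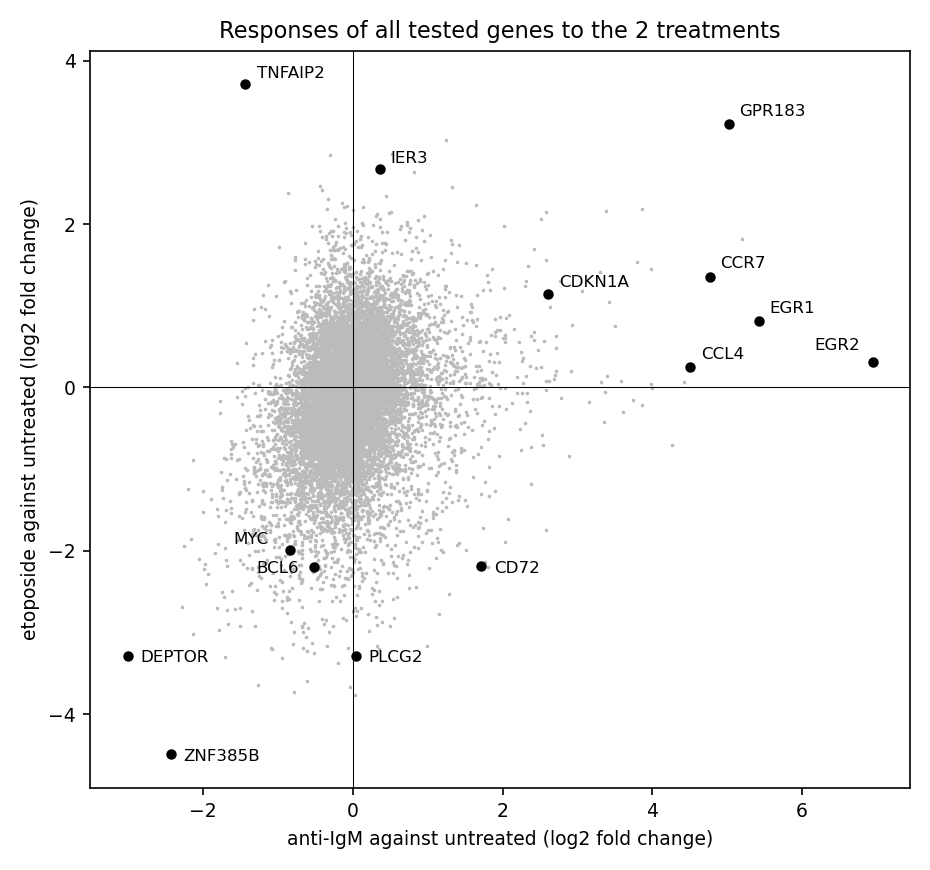
Log2 fold change of all 18282 tested genes with anti-IgM (horizontal axis) and etoposide (vertical axis), each against untreated cells, as the mean of 3 replicates. Black points are genes named in the text. EGR2 lay at 6.94 with anti-IgM and 0.31 with etoposide, CD72 at 1.71 and -2.19, and BCL6 at -0.51 and -2.19.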

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

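The tests of the normalisation, of the treatment, of exchanged dyes and of an inverted table were chosen after the result was seen, and those of sample splits and dim probes before. Genes named here because they moved in opposite directions were chosen after their values were seen.

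Opposite directions past the threshold were found for 1312 genes. Genes chosen in this way pass the limma test of the difference nearly by construction, so that test adds no support. The genes with the largest smaller change of the pair included LDLRAD4, at -1.89 ± 0.14 with etoposide and 2.03 ± 0.14 with anti-IgM, and VAV3, an exchange factor in B-cell receptor signalling, at -2.20 ± 0.11 and 1.81 ± 0.11. GRK5 stood at -2.14 and 1.76, ACP5 at -1.75 and 2.58, and CD72 at -2.19 and 1.71. TNFAIP2 went the other way, at 3.71 with etoposide and -1.45 with anti-IgM.

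The share of spots well above background in the treated channel was 59.178% on 1 etoposide array, and the next lowest of 6 was 66.9%. In the untreated channel it was 59.226% on 1 etoposide array (next lowest 65.7%) and 59.475% on 1 anti-IgM array (next lowest 65.9%). All 3 values belong to replicate 3, in the green channel of slide 3. The other array of that slide was also low in green, at 60.453%. On the other slides the green channel lay between 66.638% and 69.739%. Of 20 such checks chance alone flags about 1, but these 3 flags share a slide and a channel and are not separate.

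With 3 ratios per treatment the splits were too few for a share under 0.05. For etoposide 1 of 4 sign patterns of the ratios, the real one, gave as many as 10757 genes, and the highest other gave 0 (11487 and 125 at an unadjusted p under 0.05). For anti-IgM it was 1 of 4, with 6691 genes against 0 (8321 and 308 unadjusted). For the difference it was 1 of 10 splits, with 8060 genes against 0 (9390 and 686 unadjusted). Among the splits that, like the real one, part every same-numbered pair, the highest other was also 0.

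After etoposide, decreases of at least 2-fold outnumbered increases 2.49 to 1, with 1585 against 637. The number lower over the number higher was 4.29 among the 9141 brighter genes and 1.42 among the 9141 dimmer ones, which argues against dim probes near the background. With Agilent's own ratios it was 1.40, between the bounds set for the test of centring, and with 3 other normalisations 2.47 to 2.79. Median centring in place of loess was 1 of these and gave 2.60. With Agilent's ratios both numbers were larger, at 1789 lower and 1279 higher. Those ratios differ from the others in more than centring. Part of the excess may thus come from how the ratios are made, and centring was not separated from the rest. A response to etoposide that anti-IgM does not share stays open as a hypothesis, with a lowest value of 1.99 among the etoposide replicates and a highest of 1.0 among the anti-IgM replicates.

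The signs of the authors' deposited table oppose the dyes in the labels for 100% of the genes called with anti-IgM. Dyes exchanged in the labels of all arrays would put immediate-early genes below 0 after receptor crosslinking, but their median was 1.46 (SD 0.24 over 3 replicates). Dyes exchanged on some but not all arrays of a treatment would leave some of its arrays correlated below 0, but the lowest correlation across genes between any 2 turned arrays of a treatment was 0.607. Dyes exchanged on all 6 etoposide arrays alone would leave the anti-IgM signs unexplained. They would also turn the deviations of same-numbered ratios of the 2 treatments, which share an untreated extract, against each other, but these correlated at 0.292 or more in all 3 numbers. A table that holds untreated over treated stays open as a hypothesis. It would equal minus the mean of the treated over untreated ratios, and the table did so, within 0.0001, for replicates 1 and 2 at 100% of 40736 probes with both treatments. Dyes exchanged on all arrays would give the same equality, and the immediate-early genes argue against that. So do 2 other lists with anti-IgM, which an exchange would turn into falls, though they were not part of that test. They are activation markers (median 1.88, replicates 1.98, 1.62 and 1.85) and chemokines, cytokines and trafficking receptors (median 1.91, replicates 1.91, 2.06 and 1.96). The table leaves out replicate 3.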

How the results depend on the processing

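Scan batch as a block in the list tests was chosen after seeing the data. The counts of changed genes stayed within 1.5 times the reported ones under each change of background, normalisation, filter, probe choice, dye-swap averaging, slide and batch. They also did with each treatment fitted alone. Without replicate 1 they did not for anti-IgM (3956 against 6691) and for the difference (5370 against 8060). The slide fit took the arrays of a dye swap as separate, so its counts (11724, 7910 and 10012) do not test a slide effect. In the separate-channel fit without the replicate block, 4904 genes passed for etoposide, 1222 for anti-IgM and 5399 for the difference, and with the replicate block 10656, 6250 and 11343. The paired and unpaired fits differ by construction in whether the spread between untreated extracts enters the error. On the 6 ratios, the replicate block gave 9580 genes and 15 lists for the difference, and changed no call of a named gene. With Agilent's ratios 4866 genes were higher and 3734 lower for the difference, against 3727 and 4333, and 6383 rose and 5022 fell with etoposide, against 5060 and 5697. Median centring ended 7 list calls. The causes were not tested. Leaving out 1 replicate, with fewer samples, gave 8484 to 9826 genes for etoposide, 3956 to 4839 for anti-IgM, 5370 to 6984 for the difference, 1884 to 2346 shared calls and r of 0.252 to 0.286. The lowest counts came without replicate 1. Camera with an estimated correlation called 0 lists for etoposide, 0 for anti-IgM and 0 for the difference (2, 6 and 2 at an unadjusted p under 0.05), and fry called 17, 14 and 19. Fry added p53 targets, CREB and CRTC targets, plasma cell, histone, ribosome biogenesis, glycolysis and hypoxia genes and T and NK cell markers for etoposide. For anti-IgM it added the BCL2 family, interferon-stimulated genes and T and NK cell markers. For the difference it added p53 targets, histone genes, the BCL2 family, ribosome biogenesis genes, interferon-stimulated genes and T and NK cell markers. HLA-DOA, at 0.45 with etoposide, was at -0.113 in the mean of all its probes, which spanned -0.50 to 0.45. Over all alternatives, list results kept direction and side of the threshold 522 times, lost it 56 times and gained it 38 times. Named genes did so 4696, 130 and 24 times, and 61 of the losses, BCL6 and MYC with anti-IgM among them, came without the replicate block. Signal over background limits the 41000 probes to 24875.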

Other observations

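The tests of gene families in this part were all chosen after the results were seen. Genes were grouped by the letters that open their symbols, and the 68 families with at least 15 tested genes were tested with camera as the gene lists were.

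After etoposide, zinc-finger genes with ZNF symbols rose as a family, with 179 of 362 higher and 53 lower (median 0.23, adjusted p = 0.000415, and adjusted p = 0.759 with an estimated correlation). Of 16 DENND genes, which encode exchange factors for Rab GTPases, 14 fell and 1 rose (median -0.88, adjusted p = 0.00117, and adjusted p = 0.678 with an estimated correlation). Of 21 ARHGAP genes, which encode GTPase-activating proteins, 14 fell and 4 rose (median -0.77, adjusted p = 0.0291, and adjusted p = 0.678 with an estimated correlation). Of 21 sorting nexin genes 14 fell and 2 rose (median -0.50, adjusted p = 0.0493, and adjusted p = 0.678 with an estimated correlation). The medians kept these signs with Agilent's ratios, with median centring and without background correction, although that of ZNF genes was 0.37 with Agilent's ratios.

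With anti-IgM, 9 of 18 DUSP genes, most of which encode dual-specificity phosphatases, rose and 1 fell (median 0.25, adjusted p = 0.00925, and adjusted p = 0.987 with an estimated correlation), a sign kept under the same 3 settings. No other family passed for anti-IgM. After etoposide 10 of 18 DUSP genes rose and 2 fell (median 0.43), and the family missed the threshold in camera (adjusted p = 0.0852). Some DUSP genes are also members of the immediate-early list. The difference between the treatments passed for ZNF genes (median 0.14, adjusted p = 0.0144), DENND genes (-0.78, adjusted p = 0.0144), ARHGAP genes (-0.72, adjusted p = 0.0313) and sorting nexins (-0.39, adjusted p = 0.0313), and also for MAP and PPP genes (-0.33 and -0.34, both with adjusted p = 0.0313). With an estimated correlation adjusted p was 0.688 to 0.814 for these. With Agilent's ratios the median difference of ZNF genes was 0.28. The difference did not pass for DUSP genes (median -0.17, adjusted p = 0.736).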
